A study of Homo sapiens with 8 samples.

How the data were processed

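RNA-seq libraries of SRA01/04 cells, a line of human lens epithelial cells, were analysed from a table of gene counts. The 8 libraries fell into 2 groups of 4 by their labels: cells carrying a control short hairpin RNA (shControl) and cells carrying a hairpin against SMURF1 (shSMURF1). Both groups received TGF-β2 at 20 ng/ml for 48 h, so no library without TGF-β2 entered the comparison. The labels call the libraries biological replicates without saying whether the cultures were grown and treated separately, and p-values measure the spread between these libraries.

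Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was selected, and cDNA was primed with random hexamers; no step that marks the strand is described. The deposited values are raw read counts per gene, whole numbers with no normalization. Per the submitters' processing notes, CASAVA, fastp, HISAT2 version 2.0.5 and featureCounts version 1.5.0-p3 were used. The genome build and annotation are not given in the sources used here. The 58735 gene identifiers of the table were all found in GENCODE release 29 on GRCh38, so symbols, gene types, coordinates, exon lengths and GC content were taken from that release. Reads that match near-identical copies, such as actin paralogs, ribosomal protein pseudogenes and nuclear copies of mitochondrial genes, can be lost or split in such counts. Without strand, reads from overlapping genes on opposite strands cannot be told apart. Named genes whose models overlap another gene in this way include PRICKLE1 with PPHLN1, COL4A2 with COL4A1, ITGB4 with GALK1, GATA2 with GATA2-AS1, TLN1 with CREB3, RPL5 with DIPK1A, GINS2 with GSE1, JUNB with HOOK2, TAGLN with PCSK7, ACTA2 with FAS, LOX with SRFBP1, TGFB1 with HNRNPUL1, KRT8 with KRT18, and SMURF1 with TRRAP, among others.

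Library totals ranged from 14688651 to 17030394 counts. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 15647 genes, and library sizes were scaled by TMM. The main test was edgeR's quasi-likelihood F test (edgeR version 4.0.16 in R version 4.3.3), two-sided, of shSMURF1 against shControl with no covariate, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was counted as changed at an adjusted p under 0.05. Standard errors of log2 fold changes are the log2 fold change divided by the root of the F statistic. CPM values are counts divided by the TMM-scaled library size. The median log2 fold change of all genes tested was 0.01.

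The 35 gene lists (6 primary lists on TGF-β signalling, epithelial and mesenchymal genes and matrix, and the rest on other processes, other cell types and RNA quality) were fixed before the data were examined, as were the tests, the first set of other settings and the rule for named genes. Each list was tested with camera of limma version 3.58.1 on log2 CPM with a preset correlation between genes of 0.01, adjusted over the 35 lists. It was tested again with the correlation estimated per list and with fry. Of the 869 genes listed, 731 were tested. The named genes were SMURF1, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those with an average log2 CPM of at least 2, an adjusted p under 0.05 and no overlap between the groups, up to 4 changed members per list with the largest change, and, for the primary lists, up to 2 members with the highest expression among those not past the test. Any other gene named was chosen after its values were seen. Some genes selected by this rule, and 1 of the lists, are not reported here.

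Other settings chosen in advance were DESeq2 size factors, no scaling beyond the library total, DESeq2 version 1.42.0, limma-voom, no filter on low counts, a filter at a CPM of 1 in 4 libraries, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were the removal of each library's trend of log2 CPM with GC content, fits without mitochondrially encoded genes, and fits without genes inside chromosomal blocks. Blocks were found by segmenting the log2 fold changes of 10190 expressed genes along each chromosome, keeping segments of at least 25 genes with a median of at least 0.12 in size. The 3′ UTRs of 9976 genes were searched for sequences of 7 bases, with 3′ UTR length and GC content in the regression.

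The count test was tested on simulated counts for 15436 genes with the means and library sizes of these groups. Of 50 genes planted at each size, it recovered 46% at 1.25-fold, 74% at 1.5-fold, 90% at 2-fold and 98% at 4-fold, and called 17 other genes. In counts drawn independently for each gene, the list test found a list shifted by 0.3 on the log2 scale and called 0 others over 15647 genes. Estimated correlations in these data reached 0.59 for ribosomal protein genes and 0.66 for mitochondrially encoded genes. The simulation therefore does not measure false calls among correlated genes. The position scan recovered 80 of 80 genes of a block planted with a shift of 0.3 among 10190. Except on chromosome 17, the blocks found in these data had medians smaller in size, for which recovery was not measured. No pair of libraries agreed within sampling noise: the chi-square statistic per gene of library pairs within a group was 2.77 at least, over 12252 genes. A gene with 0 counts in a library may hold up to 3 counts at this depth, which is a CPM of 0.176 to 0.204. Such floors cover counting error only.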

Results

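Gene expression was measured in SRA01/04 cells, human lens epithelial cells immortalised with a viral large T antigen, after 48 h with 20 ng/ml TGF-β2, a growth factor that drives lens epithelial cells towards a fibrotic state. There were 4 libraries from cells with a control hairpin and 4 from cells with a hairpin against SMURF1, a HECT-type ubiquitin ligase that acts on SMAD proteins and their receptors. The comparison asks how gene expression in cells with the SMURF1 hairpin differs from that in control cells under TGF-β2. The labels name no second hairpin against SMURF1 and no rescue. For the changes below, the fall of SMURF1 therefore cannot be told apart from other differences between the shControl and shSMURF1 cells. Total counts ranged from 15000813 to 17030394 in shControl and from 14688651 to 16789144 in shSMURF1 (n = 4 each).

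SMURF1 (ENSG00000198742, GRCh38 chromosome 7, 99027438 to 99144100, minus strand) fell from 88.9 ± 3.17 CPM in shControl to 51.1 ± 0.491 CPM in shSMURF1 (mean ± SD, n = 4 each), or 57.5% of control. Every shSMURF1 library lay between 50.4 and 51.4 CPM and every shControl library between 85.8 and 93.3 CPM. The log2 fold change was −0.80 ± 0.055 (SE; adjusted p = 2.86e-09, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). SMURF1 lies in a stretch of chromosome 7 whose other expressed genes had a median log2 fold change of −0.28, described with the chromosomal positions at the end, and SMURF1 lay at −0.52 relative to that median.

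Among changed protein-coding genes with an average log2 CPM of at least 2 and no overlap between the libraries of the groups, the largest rises were in NRK, a kinase gene of the germinal centre kinase family (19.8 ± 0.821 CPM in shSMURF1, log2 fold change 3.63 ± 0.15 SE), RCAN2, a calcineurin regulator (2.95 ± 0.21), AMOT, an angiomotin that binds YAP (2.62 ± 0.11), GPRIN3 (2.21 ± 0.19) and CXCL8, the neutrophil chemokine interleukin-8 (2.17 ± 0.21). TNFAIP2, TRIL, PPP2R2B, TSHZ2 and SUCNR1, the succinate receptor, rose by 1.98, 1.89, 1.87, 1.85 and 1.83 on the log2 scale. Under the same limits the largest falls were in ACTG2, a smooth muscle actin (20.9 ± 2.94 to 2.75 ± 0.822 CPM, log2 fold change −2.91 ± 0.17), KRT19, a simple-epithelium keratin (−2.25 ± 0.059), PELI2, DSC3, a desmosomal cadherin, and TINAGL1. COL11A1, KANK1, NXF3, EFNA5 and SMOC1 followed, with log2 fold changes from −2.04 to −1.84.

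Of 15647 genes tested, 3527 changed: 1611 were higher and 1916 lower in shSMURF1 (edgeR, adjusted p under 0.05). At least 2-fold changes were found in 337 genes, 184 higher and 153 lower, and the median size of change was 0.35 on the log2 scale. In 2925 of the changed genes the groups did not overlap. Without shSMURF1 replicate 3, which stood apart from the other shSMURF1 libraries, 5348 genes passed, 2601 higher and 2747 lower. With the GC trend of each library removed as well, 4474 genes passed without it and 4426 with all libraries. The first principal component held 52.6% of the variance of the 500 most variable genes and separated the groups.

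**Figure D1:**
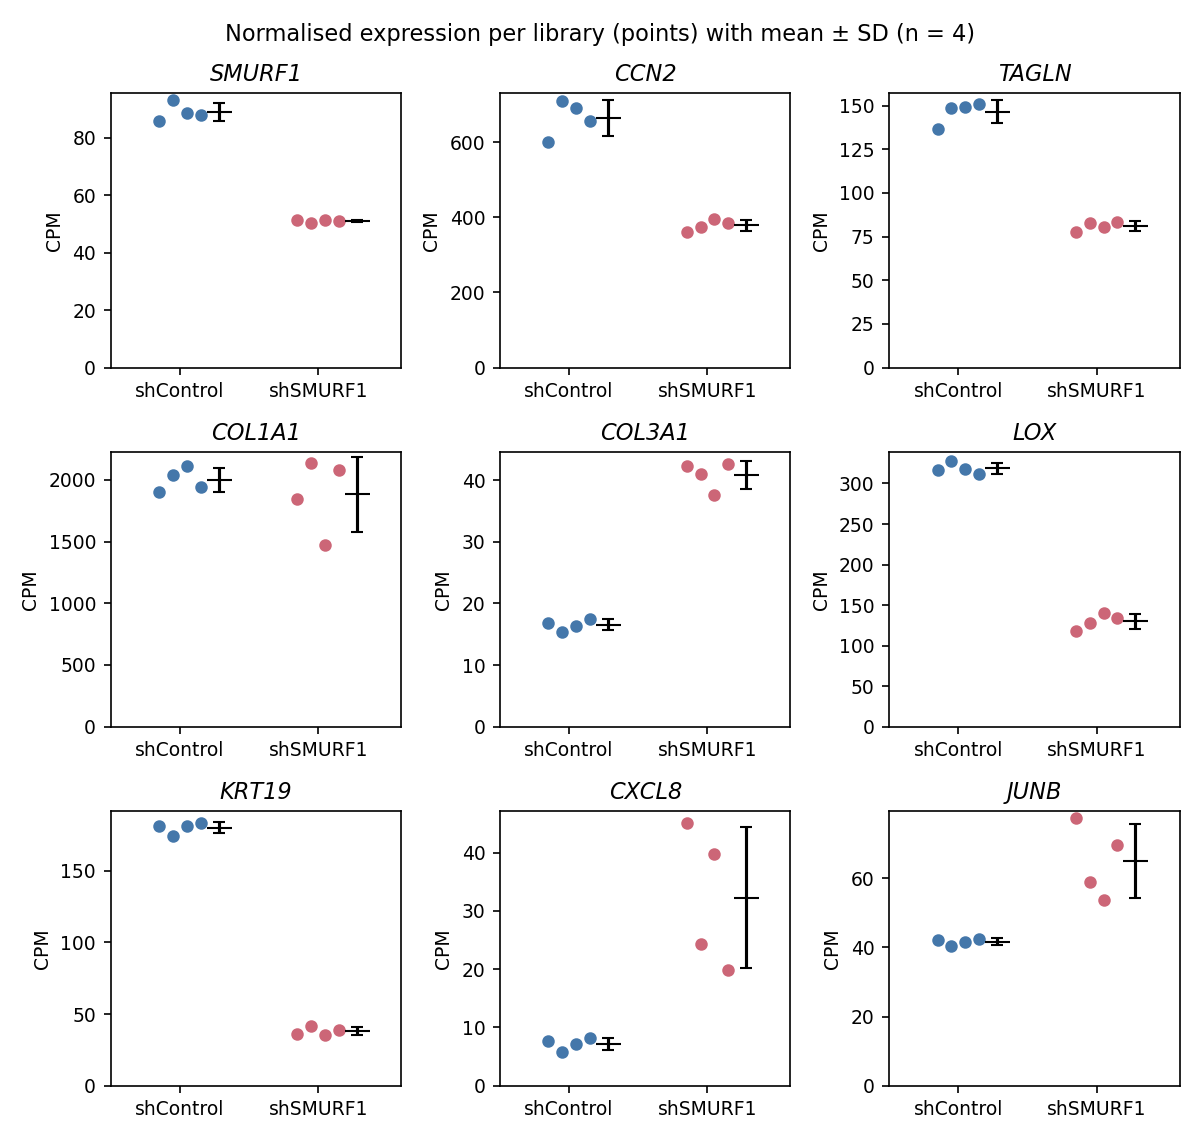
Normalised expression (CPM) of 9 genes in each library (points; shControl blue, shSMURF1 red) with the mean and SD of the 4 libraries (black). SMURF1, CCN2, TAGLN, LOX and KRT19 were lower in every shSMURF1 library and COL3A1, CXCL8 and JUNB higher, while the groups overlapped for COL1A1 (2001 ± 96.2 against 1884 ± 303 CPM).

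Target genes of TGF-β and SMAD proteins moved in both directions. TAGLN, an actin-binding protein of smooth muscle, fell from 146 ± 6.65 to 81.1 ± 2.61 CPM (log2 fold change −0.85 ± 0.053 SE, edgeR adjusted p = 8.31e-10). CCN2, connective tissue growth factor (−0.81 ± 0.053), and TSPAN2, a tetraspanin (46.5% of control), also fell, whereas JUNB rose by 0.64. Of 31 tested SMAD targets, 8 rose, 11 fell and 12 did not pass, with the same 8 and 11 adjusted over the list alone. The list as a whole did not shift in a shared direction relative to other genes (camera adjusted p = 0.314, or 0.528 with an estimated correlation). That test does not measure how often members changed in either direction. Of all genes tested, 22.5% changed, a smaller share than in this list. COL1A1 and COL4A2, at 2001 and 652 CPM in shControl, did not pass (−0.09 ± 0.080 and 0.05 ± 0.068), although COL4A2 did without shSMURF1 replicate 3 (adjusted p = 0.00309). With the GC trend of each library removed, COL4A2 lay at −0.030 and did not pass (edgeR adjusted p = 0.603). In that fit COL1A1 passed as lower (edgeR adjusted p = 0.00921). TSPAN2 lies inside a chromosomal block of lower expression, and such blocks held 4 of the 11 members that fell.

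Among components of the TGF-β and BMP pathways, BMPR1B, a BMP receptor, fell to 22.4% of control at a low level (2.54 ± 0.760 to 0.564 ± 0.239 CPM). BMP4 fell to 50.1% of control and THBS1, an activator of latent TGF-β, to 65.8%, while TGFB1 (0.08 ± 0.056) and USP11 (−0.05 ± 0.048) did not pass. Of 33 components, 3 rose and 11 fell (4 and 11 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.149; adjusted p = 0.321 with an estimated correlation). The 3 that rose were ENG, SMAD3 and SMAD6, with log2 fold changes of 0.43, 0.15 and 0.26, named after their values were seen. All 3 lie outside chromosomal blocks. There were 5 higher components without shSMURF1 replicate 3, where TGFB1 (adjusted p = 0.00261) and GATA2, a BMP target (0.000698), also passed. With the GC trend of each library removed, TGFB1 lay at −0.0089 and did not pass (edgeR adjusted p = 0.884), although 6 components were then higher. Without shControl replicate 1 or 4 or shSMURF1 replicate 2 or 4 only 1 component was higher, as without genes in chromosomal blocks. Of 17 target genes of BMP and SMAD1/5, 3 rose and 7 fell, with the same counts adjusted over the list alone. NOG, a secreted BMP antagonist (−0.91 ± 0.079), BAMBI, a pseudoreceptor (−0.73 ± 0.14), and ID4 (−0.56 ± 0.14) fell and UNC5B rose (0.82 ± 0.20). SMAD7, the inhibitory SMAD, did not pass (−0.07 ± 0.080), nor did GATA2 (0.14 ± 0.082), nor the list (camera adjusted p = 0.156; adjusted p = 0.528 with an estimated correlation).

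Genes of epithelial-mesenchymal transition split. COL3A1 and POSTN, both matrix genes of activated fibroblasts, rose about 2.47-fold and 2.45-fold (log2 fold changes 1.30 ± 0.077 and 1.29 ± 0.093), while LOX, a collagen cross-linking enzyme, fell from 319 ± 6.78 to 130 ± 9.24 CPM and CDH11, a mesenchymal cadherin, fell from 14.9 ± 0.294 CPM to 50.03% of that level. Of 27 members, 7 rose and 10 fell (8 and 12 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.527; adjusted p = 0.823 with an estimated correlation). CDH2, N-cadherin, lay just outside the threshold (−0.14 ± 0.049, edgeR adjusted p = 0.0519), and passed it with DESeq2 (adjusted p = 0.0208), with limma-voom (0.0421) and without shSMURF1 replicate 3 (0.000763). Of 21 epithelial genes tested, 2 rose and 7 fell, the same adjusted over the list alone. Without shControl replicate 1 only 4 were lower, and leaving out any library but shSMURF1 replicate 3 left 1 higher. KRT19 and CLDN1, a tight junction protein (−0.42 ± 0.092), fell and LAMB3, a laminin chain, rose (0.50 ± 0.077). KRT8 (−0.06 ± 0.049) and KRT18 (−0.02 ± 0.050), the main keratin pair of simple epithelia, did not pass, nor did the list (camera adjusted p = 0.135; adjusted p = 0.370 with an estimated correlation). CDH1, E-cadherin, had 4 counts over the 8 libraries together and was not tested.

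Collagens and other matrix proteins changed often and in both directions. Of 47 tested, 18 rose and 12 fell (21 and 13 adjusted over the list alone), with LUM, a small proteoglycan, COL3A1 and POSTN among those that rose and COL11A1, a fibrillar collagen (22.4 ± 2.12 to 5.45 ± 0.954 CPM), among those that fell. LUM rested on 2 to 9 counts per shControl library. COL6A2 did not pass (0.16 ± 0.069), but did without shSMURF1 replicate 3 (adjusted p = 2.38e-07) and with no filter on low counts (0.0119). The shSMURF1 libraries left in the fit without that replicate share a trend with GC content, described below. The list did not pass with all libraries (camera adjusted p = 0.314; adjusted p = 0.823 with an estimated correlation), but did without shSMURF1 replicate 3 (adjusted p = 0.0371) and without genes inside chromosomal blocks (adjusted p = 0.0226). The fit without block genes leaves out 7 members, of which 0 rose and 3 fell. COL11A1, which is among them, lay at −1.77 relative to the median of its block. With the GC trend of each library removed the list did not pass, with 18 members higher and 15 lower and a median log2 fold change of −0.0037 against 0.07. Among 33 matrix remodelling enzymes, 11 rose and 9 fell (12 and 10 adjusted over the list alone), led by ADAMTS14 (1.61 ± 0.24) and ADAMTS1 (−1.36 ± 0.099), and among 24 integrins, 7 rose and 6 fell, the same adjusted over the list alone, led by ITGB6, ITGA7, ITGB4 and ITGA4, which rose by 1.09, 0.87, 0.72 and 0.68. Neither list passed (camera adjusted p = 0.821 and 0.770; adjusted p = 0.850 and 0.823 with an estimated correlation). The mean of the matrix remodelling list was 0.05 and its median −0.04, and those of the integrins were 0.07 and −0.01.

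**Figure D2:**
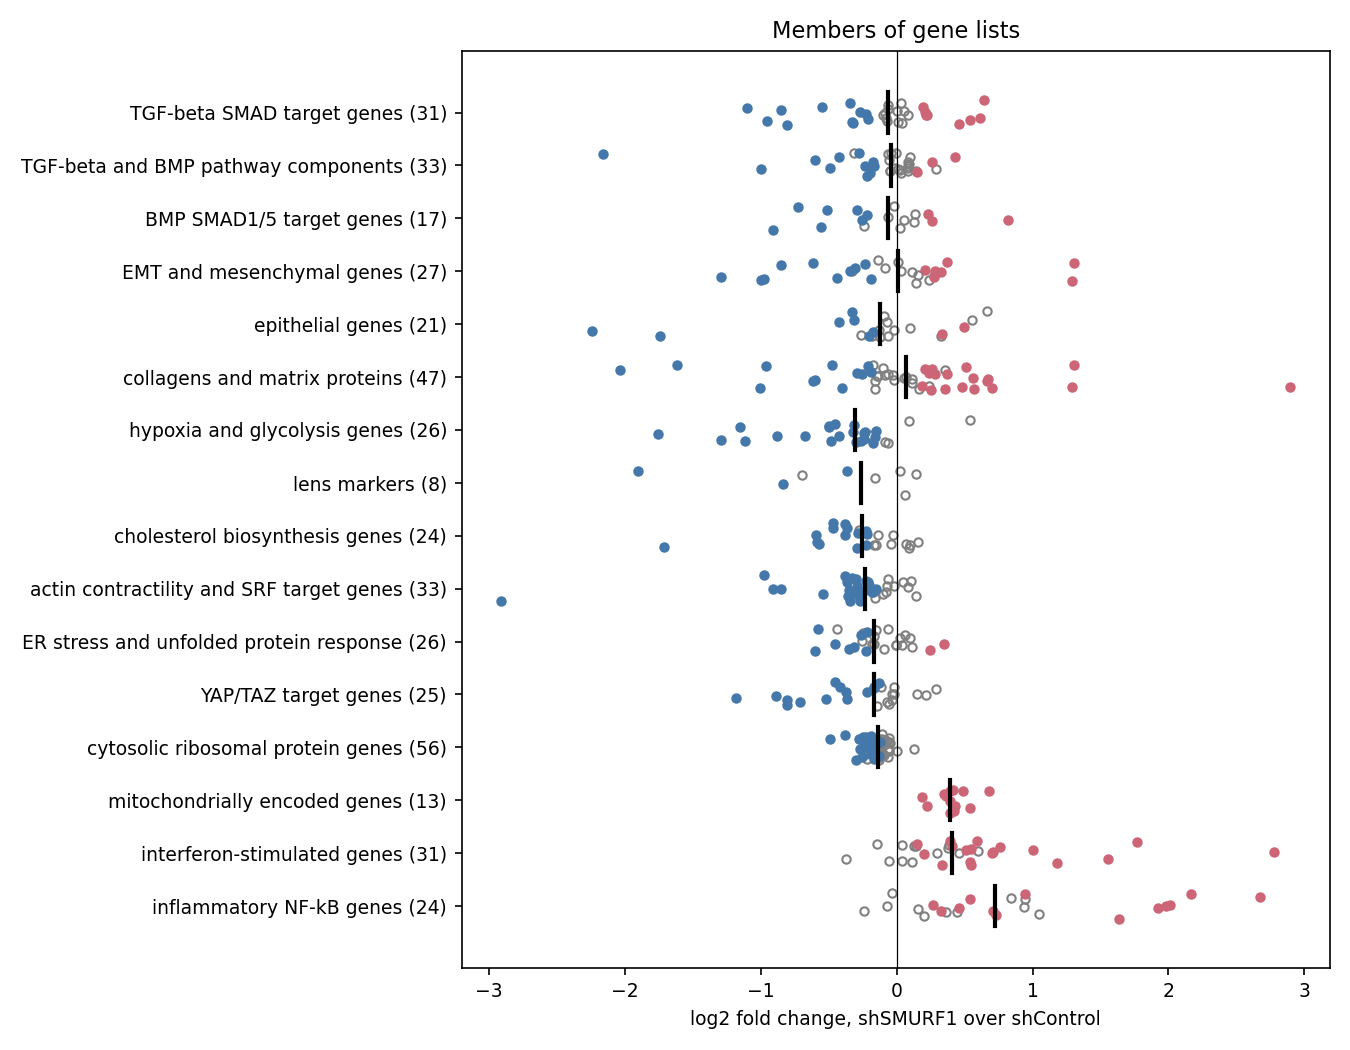
Log2 fold change of shSMURF1 over shControl for each tested member (points) of the primary lists and of the lists past the camera threshold, with the number tested in parentheses; filled points passed the test (red higher, blue lower), open points did not, and black bars are medians. Of the hypoxia and glycolysis genes 21 of 26 fell, and of the NF-kB genes 13 of 24 rose.

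Genes of the contractile actin cytoskeleton, many of them targets of serum response factor, fell together. Of 33 tested, 23 fell and 0 rose (24 and 1 adjusted over the list alone), among them ACTG2, ACTA2, the α-smooth muscle actin of myofibroblasts (8.15 ± 1.31 to 4.15 ± 0.903 CPM), CALD1, caldesmon (−0.91 ± 0.049), and TAGLN (camera adjusted p = 3.26e-09; adjusted p = 0.183 with an estimated correlation). At an unadjusted p under 0.05, edgeR put 1 member higher, and DESeq2 and limma-voom called 0 as higher. In the fit without shSMURF1 replicate 3, 2 members were higher. CALD1 lies in the chromosome 7 block of lower expression, and 20 of the 23 genes that fell lie outside all blocks. Target genes of YAP and TAZ, the transcriptional coactivators of the Hippo pathway, also fell: 14 of 25 were lower and 0 higher (14 and 1 adjusted over the list alone), with ANKRD1 (181 ± 9.50 to 79.7 ± 9.75 CPM), CCN1 (−0.89 ± 0.048), WWC1 (−0.81 ± 0.077) and CCN2 among them (camera adjusted p = 5.94e-06; adjusted p = 0.234 with an estimated correlation). For this list edgeR put 2 members higher at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. A single member was higher without shSMURF1 replicate 1 or 3. CCN1 and 3 more of the 14 lie in blocks.

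Genes induced by hypoxia, with the glycolytic enzymes, were the list with the smallest camera p. Of 26 genes, 21 fell and 0 rose (21 and 1 adjusted over the list alone): CA9, a carbonic anhydrase (43.1 ± 1.93 to 12.8 ± 1.19 CPM), LOX, ADM, adrenomedullin (−1.16 ± 0.075), and NDRG1 (−1.12 ± 0.072) fell furthest (camera adjusted p = 2.38e-11; adjusted p = 0.134 with an estimated correlation). At an unadjusted p under 0.05, edgeR put 1 of them higher, and DESeq2 and limma-voom called 0, and 1 was higher without shSMURF1 replicate 1. Cholesterol synthesis genes fell in 14 of 24 cases with 0 higher (18 and 1 adjusted over the list alone), among them SC5D, a sterol desaturase (61.9 ± 4.05 to 41.0 ± 5.64 CPM), INSIG1 (−0.59 ± 0.063) and CYP51A1 (−0.57 ± 0.13) (camera adjusted p = 1.0e-05; adjusted p = 0.249 with an estimated correlation). Of the 14, 4 lie in blocks of lower expression, INSIG1 and CYP51A1 on chromosome 7 among them. For this list edgeR put 1 member higher at an unadjusted p under 0.05, DESeq2 and limma-voom called 0, and 2 were higher without shSMURF1 replicate 3.

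Among 26 genes of endoplasmic reticulum stress, 8 fell and 2 rose (9 and 2 adjusted over the list alone), led by PHGDH (329 ± 14.6 to 217 ± 8.67 CPM) and PSAT1 (−0.58 ± 0.078), both enzymes of serine synthesis, and SESN2 (−0.45 ± 0.083). The list passed (camera adjusted p = 0.0213; adjusted p = 0.183 with an estimated correlation), but not once the GC trend of each library was removed (adjusted p = 0.0593) or without genes in blocks (adjusted p = 0.0720), where PHGDH and SESN2 lie. Leaving out any library but shSMURF1 replicate 3 left 0 or 1 of its members higher. Of 24 p53 targets, 7 fell and 2 rose, the same adjusted over the list alone: FAS, a death receptor (−0.95 ± 0.10), and GADD45A (−0.45 ± 0.077) fell and GDF15 rose (0.89 ± 0.11). The p53 list did not pass (camera adjusted p = 0.135; adjusted p = 0.555 with an estimated correlation), but did without shSMURF1 replicate 1 (adjusted p = 0.0188) and under fry (adjusted p = 0.0384). Of the p53 targets 5 were higher without shSMURF1 replicate 3, and leaving out any other library except shControl replicate 3 left 1, while 1 was higher and 4 were lower without genes in blocks. The 2 p53 targets that rose lie outside blocks. Of 27 NRF2 and oxidative stress genes, 3 rose and 7 fell (3 and 8 adjusted over the list alone), with ABCC3 higher (0.77 ± 0.10) and GCLM, a subunit of the glutathione-forming ligase, lower (−0.74 ± 0.075). Of 18 heat shock genes, 1 rose, HSP90AA1 (0.18 ± 0.047), and 3 fell, HSPB1 (−0.23 ± 0.049) among them, the same adjusted over the list alone. HSPB1 lies in the chromosome 7 block of lower expression, at 0.05 relative to its median of −0.28. Heat shock genes numbered 3 higher and 5 lower without shSMURF1 replicate 3, and without shSMURF1 replicate 2, 2 were higher. Neither list passed (camera adjusted p = 0.384 and 0.770; adjusted p = 0.809 and 0.874 with an estimated correlation).

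Inflammatory genes controlled by NF-kB rose. Of 24 tested, 13 rose and 0 fell (15 and 1 adjusted over the list alone), among them CXCL8 (7.15 ± 1.04 to 32.3 ± 12.1 CPM), CXCL1, TNFAIP2 and CSF2, the granulocyte-macrophage growth factor gene (camera adjusted p = 1.44e-07; adjusted p = 0.234 with an estimated correlation). CSF2 rested on 1 to 6 counts per shControl library. Interferon-stimulated genes rose in 18 of 31 cases with 0 lower (19 and 1 adjusted over the list alone), including the oligoadenylate synthetase genes OAS1 (2.78 ± 0.43) and OASL (1.55 ± 0.26) and MX1, an antiviral GTPase (1.18 ± 0.26), all of them at 1.95 CPM or less in shControl (camera adjusted p = 2.33e-07; adjusted p = 0.183 with an estimated correlation). In both lists edgeR put 1 member lower at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. In NF-kB genes 1 was lower without shControl replicate 1, and 1 interferon-stimulated gene without shSMURF1 replicate 1 or 4.

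Among 17 ubiquitin ligases related to SMURF1, HECW1 rose (0.62 ± 0.21) and 5 fell (2 and 6 adjusted over the list alone), including NEDD4L (−0.41 ± 0.061), CUL1 (−0.29 ± 0.061) and TRIM33 (−0.27 ± 0.054). HECW1, CUL1 and TRIM33 lie in blocks with medians of 0.20, −0.28 and −0.27. HECW1 did not pass with DESeq2 (adjusted p = 0.0764), with the replicate number as a block (0.0574) or without any library except shControl replicate 4 (0.0514 to 0.129). Ligases counted as lower were 8 without shSMURF1 replicate 3 and 3 without genes in blocks, and those counted as higher were 3 with the GC trend of each library removed and 0 without genes in blocks. Of 23 genes whose proteins have been reported as SMURF1 substrates, 3 rose and 3 fell, the same adjusted over the list alone: PRICKLE1, a planar polarity gene (1.04 ± 0.27) that overlaps the more abundant PPHLN1 on the opposite strand (average log2 CPM 0.76 against 5.96), and KLF2 (0.76 ± 0.10) rose, and TLN1, talin (−0.31 ± 0.046), and TGFBR1, the type I TGF-β receptor (−0.23 ± 0.061), fell. Of 14 Notch genes, 1 rose and 4 fell (2 and 5 adjusted over the list alone): NOTCH3 rose (0.71 ± 0.081), and JAG1, a Notch ligand (−0.97 ± 0.092), NOTCH2 (−0.54 ± 0.046) and RBPJ (−0.34 ± 0.064) fell. Notch genes counted as higher were 4 without shSMURF1 replicate 3 and 2 without shControl replicate 1. Of 13 β-catenin targets, 3 rose and 6 fell, the same adjusted over the list alone, with TNFRSF19 (−0.86 ± 0.11) and LEF1 (−0.82 ± 0.15) lower and NOTUM higher (0.75 ± 0.13). NOTUM lies in the chromosome 17 block of higher expression (median 0.33). Without genes in blocks 0 of 11 β-catenin targets were higher, and without shControl replicate 1 or 2 or shSMURF1 replicate 2 or 4 only 1 was. Of the 3 that rose, 2 lie outside blocks and lost the call in the fit without block genes. Camera adjusted p-values for these lists, in that order, were 0.318, 0.821, 0.324 and 0.244, none of them past the threshold, and 0.685, 0.850, 0.540 and 0.374 with an estimated correlation.

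Cell cycle genes changed in both directions. Of 35 genes of G1/S and replication, 6 rose and 5 fell (6 and 6 adjusted over the list alone), with CCNE1, cyclin E (−0.48 ± 0.070), and RRM2 (−0.39 ± 0.073) lower and GINS2 (0.31 ± 0.076) higher. Of 36 mitotic genes, 2 rose and 7 fell, the same adjusted over the list alone, including BIRC5, survivin (0.39 ± 0.046), in the chromosome 17 block of higher expression, and CDCA8 (−0.31 ± 0.060) and KIF2C (−0.28 ± 0.049) in a chromosome 1 block of lower expression. Leaving out shSMURF1 replicate 3 put 10 genes of G1/S higher and 9 lower, and 15 mitotic genes lower. Without genes in blocks, 3 of 29 genes of G1/S and 2 of 29 mitotic genes were lower and 0 mitotic genes higher. Of the 2 mitotic genes that rose, 1 lies outside blocks. Leaving out any library but shSMURF1 replicates 3 and 4 left 1 mitotic gene higher. Camera adjusted p-values were 0.985 and 0.336 (adjusted p = 0.987 and 0.823 with an estimated correlation).

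Of 35 lens markers, 8 were expressed well enough to test, and 3 fell with 0 higher, the same adjusted over the list alone, among them GJA1, a gap junction connexin (−0.83 ± 0.063), and SIX3, a homeobox gene (16.2 ± 1.37 to 12.6 ± 0.975 CPM). At an unadjusted p under 0.05, edgeR put 0 lens markers higher, as did DESeq2 and limma-voom after adjustment. The list passed narrowly (camera adjusted p = 0.0431; adjusted p = 0.234 with an estimated correlation), and not without shSMURF1 replicate 3 (adjusted p = 0.190), shControl replicate 1 (0.115) or 4 (0.114) or shSMURF1 replicate 4 (0.121), and SIX3 did not pass without shControl replicate 4 (0.0531). Among fibroblast markers, 4 of 10 rose and 1 fell (5 and 1 adjusted over the list alone): LUM, COL3A1 and PDGFRB (0.38 ± 0.059) rose, while COL1A2, the partner chain of COL1A1 (244 ± 8.27 to 121 ± 4.86 CPM), fell and lies in the chromosome 7 block. Of 7 endothelial markers, ESAM (0.98 ± 0.19) and TIE1 (0.27 ± 0.083) rose, with 3 higher and 1 lower adjusted over the list alone. Of 3 haematopoietic markers CD14 rose (0.95 ± 0.12), of 4 keratinocyte markers IVL rose (1.38), and of 6 markers of pigment epithelium and melanocytes SERPINF1 rose (0.68 ± 0.20) and MITF fell (−0.40 ± 0.086), with the same counts adjusted over each list alone. TIE1 did not pass without any library except shSMURF1 replicate 3 (adjusted p = 0.0550 to 0.0880), SERPINF1 did not without shControl replicate 4 (0.0669) or shSMURF1 replicate 2 (0.0508), and 0 keratinocyte markers rose without shControl replicate 2 or 3 or shSMURF1 replicate 1 or 4. The fibroblast, endothelial, haematopoietic, keratinocyte and pigment lists did not pass (camera adjusted p = 0.0965, 0.324, 0.135, 0.873 and 0.440; adjusted p = 0.370, 0.555, 0.332, 0.878 and 0.571 with an estimated correlation). Without genes in blocks the fibroblast list passed as higher (adjusted p = 0.00546). That fit leaves out COL1A2, the only member that fell, which lay at −0.73 relative to the median of its block.

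Mitochondrially encoded transcripts were higher in shSMURF1 and ribosomal protein transcripts lower. All 13 mitochondrial genes rose, by a median of 0.39 on the log2 scale, MT-CYB from 2843 ± 131 to 3981 ± 495 CPM (camera adjusted p = 9.36e-07; adjusted p = 0.360 with an estimated correlation). Their share of all counts was 4.24% ± 0.156 in shControl and 5.45% ± 0.591 in shSMURF1 (SD, n = 4; exact permutation test, two-sided p = 0.0286, the smallest this design allows), with 6.34% in shSMURF1 replicate 3. Of 56 cytosolic ribosomal protein genes 24 fell and 0 rose (33 and 0 adjusted over the list alone), RPL5 (−0.38 ± 0.048) and RPL11 (−0.30 ± 0.062) among them, both in chromosome 1 blocks (camera adjusted p = 6.74e-08; adjusted p = 0.528 with an estimated correlation). DESeq2 and limma-voom also called 0 ribosomal protein genes higher, and edgeR put 0 higher at an unadjusted p under 0.05. Leaving out shSMURF1 replicate 3 put 42 of them lower. Immediate early genes went both ways, 3 higher and 3 lower of 16, the same adjusted over the list alone, with JUNB (0.64 ± 0.089) higher and DUSP1 (−0.72 ± 0.061) and JUN (−0.37 ± 0.054) lower, and of 11 histone genes H3C10 rose 2.14-fold and H2AC6 fell (−0.56 ± 0.15), the same adjusted over the list alone. The immediate early genes counted as higher were 5 without shSMURF1 replicate 3, and H3C10 did not pass with DESeq2 (adjusted p = 0.0667) or without shControl replicate 1, 2 or 3 or shSMURF1 replicate 2 or 4 (0.0630 to 0.152). Neither of these lists passed (camera adjusted p = 0.770 for each; adjusted p = 0.839 and 0.823 with an estimated correlation).

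Libraries also differed by GC content of the genes. The median deviation of the fifth of genes with the highest GC content minus that of the fifth with the lowest lay between −0.05 and 0.04 (log2) in the shControl libraries. It was 0.22, 0.26 and 0.32 in shSMURF1 replicates 1, 2 and 4 and −0.20 in shSMURF1 replicate 3. A fit without shSMURF1 replicate 3 therefore compares shSMURF1 libraries that share a positive trend with shControl libraries that hardly have it. For genes that passed only in that fit, the fit cannot tell a group difference apart from this trend. With these trends removed, 4426 genes changed, 2185 higher and 2241 lower (edgeR), and 4474 without shSMURF1 replicate 3, 2208 higher and 2266 lower.

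Along the chromosomes, neighbouring genes shifted together in 7 blocks, found after the data were seen. On chromosome 7, from 72.9 to 159.0 Mb (GRCh38), 286 expressed genes had a median log2 fold change of −0.28, and 92.3% of them were negative; this block holds SMURF1, CALD1 and COL1A2. On chromosome 17, from 68.9 to 83.1 Mb, 136 genes had a median of 0.33 and 97.1% were positive, ITGB4 and BIRC5 among them. The other blocks were on chromosome 1 (20.6 to 56.6 Mb, median −0.19, and 58.7 to 121.4 Mb, median −0.27), chromosome 3 (139.4 to 198.0 Mb, −0.16), chromosome 7 (36.3 to 70.8 Mb, 0.20) and chromosome 14 (24.4 to 76.3 Mb, −0.17). Together they held 12.4% of the genes tested and 24.8% of those that changed (875 genes, 822 with the sign of their block). Inside blocks 44.9% of genes changed and outside 19.4%, where 1386 rose and 1266 fell. COL1A2 and CALD1 lay at −0.73 and −0.63 relative to the median of their block. BMP4, GCLM, NOTCH2, CLDN1, GADD45A and JUN, in blocks of lower expression on chromosomes 1, 3 and 14, lay at −0.82, −0.47, −0.27, −0.26, −0.18 and −0.10 relative to theirs.

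**Figure D3:**
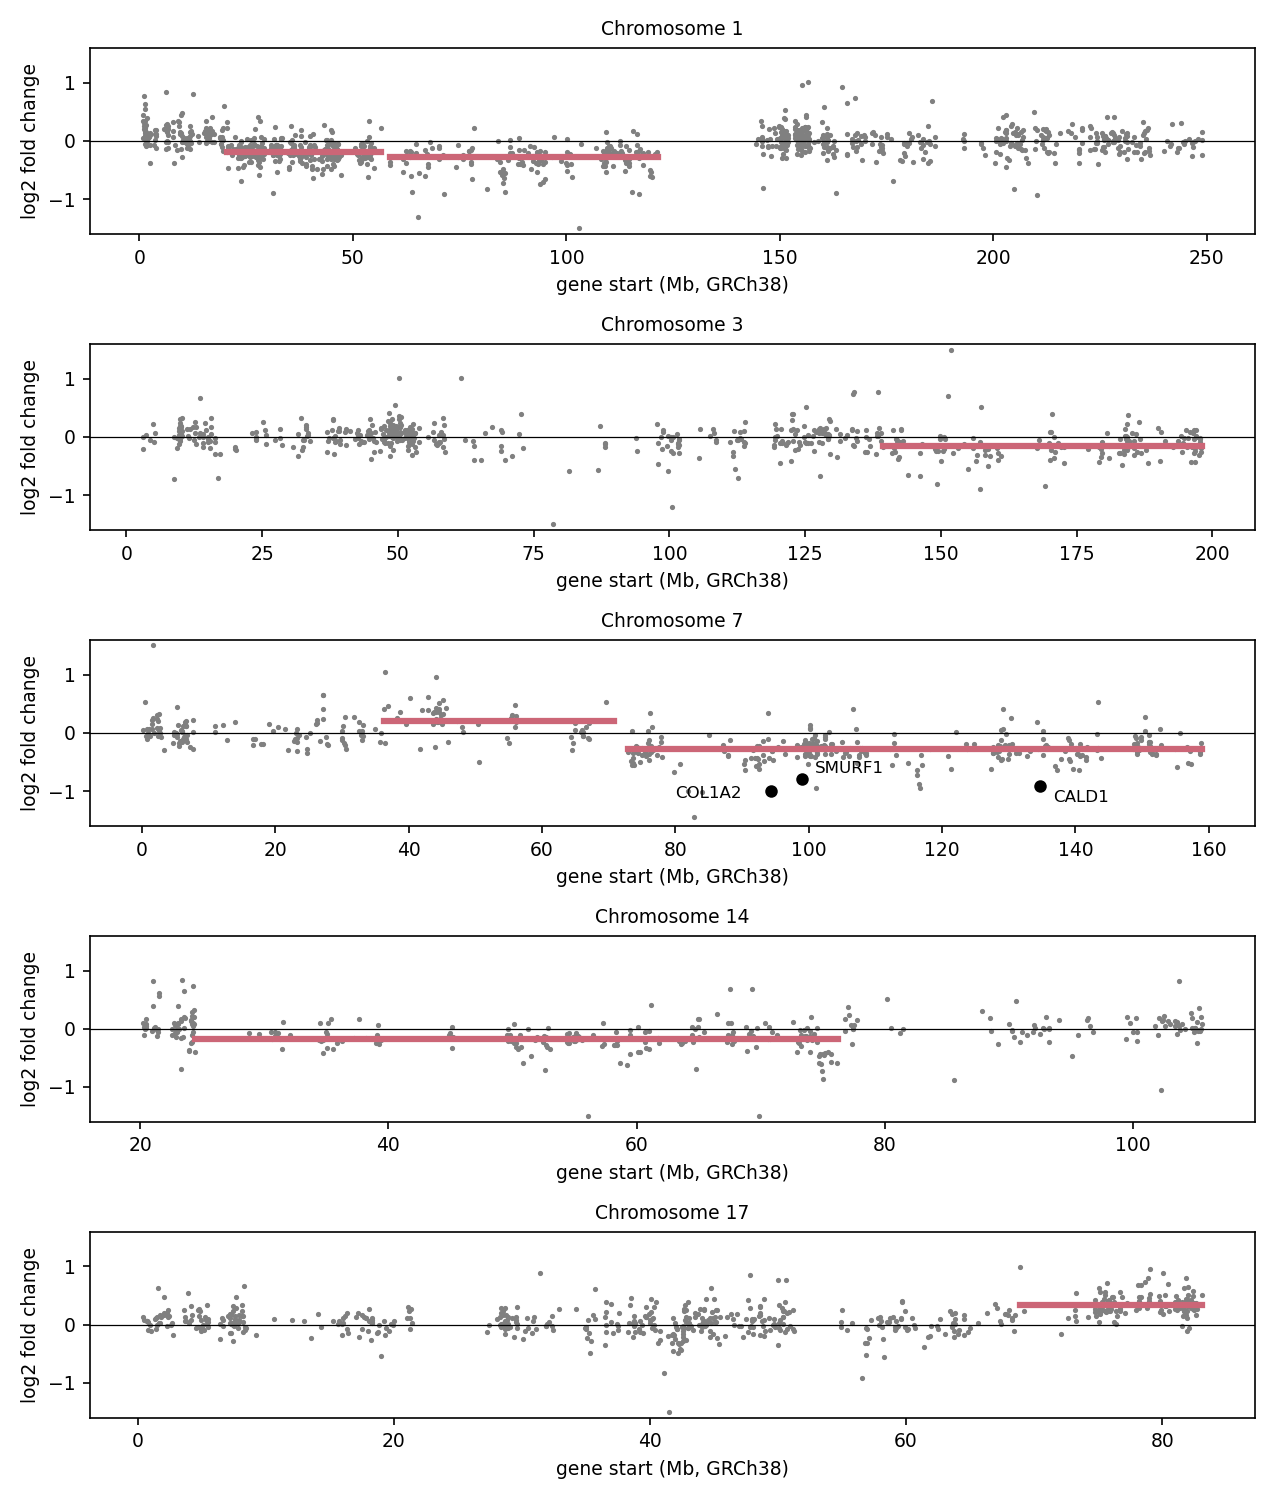
Log2 fold change of shSMURF1 over shControl (points, drawn within ±1.5) against gene start in Mb for expressed genes of the 5 chromosomes with blocks; red bars span each block at its median. The block on chromosome 7 from 72.9 Mb sits at −0.28, with SMURF1, CALD1 and COL1A2 (black) below it.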

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

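The tests with the GC trend removed and without mitochondrially encoded genes were chosen only after shSMURF1 replicate 3 was seen to stand apart. Each group of 4 libraries was searched for a library far from the other 3, over 294 groups of values, and 16 were found where chance gives 14.7. Of these, 8 fell on shSMURF1 replicate 3. In that library mitochondrial transcripts took 6.34% of counts (5.07 to 5.22% in the other 3), the 10 largest genes took 7.04% (6.03 to 6.18%), and the second principal component was 14.9 (−6.66 to −3.92). Among the shSMURF1 libraries it also had the highest CPM of NXF3 (3.62), BMPR1B (0.920), CUL1 (109) and MT-CYB (4721) and the lowest of COL6A2 (655).

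For the distance of shSMURF1 replicate 3, a trend with GC content was the leading technical candidate. Its mean distance to the other shSMURF1 libraries was 1.63 times their distance to each other. The ratio fell to 1.16 with the GC trend of each library removed, so that trend may account for most of the distance. It stayed over the bound of 1.1 set beforehand (bootstrap SE 0.011). The bootstrap resampled genes and holds no spread between libraries, and this library was picked for standing apart. Whether a part of the distance remains therefore cannot be told. Leaving out mitochondrially encoded genes left the ratio at 1.64, but these 13 genes held only 0.196% of the squared distance, so that test decides nothing and the mitochondrial share cannot be told apart. A difference in the culture or in library making stays open, and no biological explanation was tested within this group.

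The remaining 8 were single values. TAGLN was low in shControl replicate 1 (137 CPM), ITGA4 was high in shControl replicate 2 (30.1), OAS1 was high in shControl replicate 3 (0.685), RBPJ was low in shControl replicate 4 (107) and SIX3 was high there (18.3). TGFBR3 (9.80) and ID4 (8.77) were high in shSMURF1 replicate 1, and TNFRSF19 was low in shSMURF1 replicate 2 (8.53).

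Other splits of the 8 libraries into 4 and 4 were fitted in the same way. The real split was the only 1 of 35 to reach its count of 3527 changed genes, and the highest other count was 1. For changes of at least 2-fold it was again 1 of 35, with 337 genes against 1. In the other splits the group difference adds to the spread within a side, which by itself lowers their counts. The comparison of these 2 counts therefore does not exclude chance, and 1 of 35 is the smallest share these splits allow. For gene lists past the camera threshold the real split also stood alone, 1 of 35, but with 10 lists against 9 in the highest other split. The 16 splits that set 3 libraries of a group with 1 of the other keep part of the group difference and put 3 to 9 lists past, so they do not measure chance. Of the 18 splits with 2 libraries of each group on either side, 9 put at least 1 list past and none more than 3. In these 18 the group difference adds to the spread within each side. A camera p as small as the real p was reached in 2 of the 18 for ribosomal protein genes, in 1 for lens markers and in 0 for the other 8 lists past the threshold.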

How the results depend on the processing

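Fits with the GC trend removed, without mitochondrially encoded genes and without genes in chromosomal blocks were added after seeing the data. The log2 fold change of SMURF1 ranged from −0.82 to −0.78 over all settings. The count of changed genes ranged from 2499 (without genes in blocks) to 5348, and of those changed at least 2-fold from 260 to 429. No gene called in both a setting and the main analysis changed sign. With no scaling beyond the library total, 52.7% of changed genes were higher, against 45.7%. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.03, −0.01, −0.07 and 0.03, and only number 4 had its own number as its best partner. With the replicate number as a block 3192 genes changed, and the lens list was not past the threshold (adjusted p = 0.0774). Leaving out a library in turn gave 2763 to 5348 changed genes and 1216 to 2601 higher, with the highest values without shSMURF1 replicate 3. On all genes tested, the first principal component held 40.3% of the variance.

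Under fry, which tests a list without comparing it with other genes, SMAD targets (adjusted p = 0.00154), pathway components (0.00185), BMP targets (0.00809) and epithelial genes (0.000876) passed, all lower. So did matrix remodelling enzymes (0.00688), β-catenin targets (0.000986), Notch genes (0.00809), ubiquitin ligases (0.0280), p53 targets (0.0384) and pigment markers (0.0171) as lower, and fibroblast (0.00565) and haematopoietic markers (0.00161) as higher. The collagen list passed without shSMURF1 replicate 3 (adjusted p = 0.0371; 0.0371 to 0.544 leaving out each library) and without block genes (0.0226). The fit without block genes leaves out 3 of its members that fell and 0 that rose. Pathway components counted as higher were 5 without shSMURF1 replicate 3 and 6 with the GC trend removed, against 3, and SMURF1 substrates 5 higher and 5 lower with the GC trend removed, against 3 and 3. COL1A1 (adjusted p = 0.00921) and KRT8 (0.0196) passed as lower with the GC trend removed. That setting also put 1 member higher in the actin, YAP/TAZ and hypoxia lists and 1 lower in the NF-kB and endothelial lists, against 0 in each, and 2 heat shock genes higher, against 1. With the replicate block 1 epithelial, 1 mitotic and 1 p53 gene were higher, against 2 in each list, and 2 Notch genes, against 1. With DESeq2 1 p53 gene, 2 heat shock genes and 0 keratinocyte markers were higher, against 2, 1 and 1. With no scaling 1 YAP/TAZ gene, 2 Notch genes and 2 heat shock genes were higher, against 0, 1 and 1. With no filter on low counts 2 Notch genes and 1 mitotic gene were higher, and at a CPM of at least 1, 0 keratinocyte markers. Without block genes 1 endothelial marker and 0 histone genes were higher, against 2 and 1, and 0 fibroblast markers lower, against 1. Of the 11 histone genes tested, 0 lie in blocks.

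Some results far from the threshold changed direction. Without block genes these were matrix remodelling enzymes (adjusted p = 0.971), integrins (0.835) and G1/S genes (0.799). The G1/S list also turned under fry (0.822), with a CPM of at least 1 (0.964) and with the GC trend removed (0.789), and keratinocyte markers turned with the replicate block (0.889). Leaving out libraries in turn changed the direction of G1/S genes (0.766 to 0.952), SMURF1 substrates (0.726 to 0.969), heat shock genes (0.632 to 0.942), keratinocyte markers (0.766 to 0.969) and immediate early genes (0.382 to 0.789). Of genes not past the test, log2 fold changes ranged from −0.154 to 0.017 for COL1A1, −0.112 to 0.0096 for SMAD7 and −0.051 to 0.0092 for KRT18 leaving out libraries. COL4A2 was −0.030 and TGFB1 −0.0089 with the GC trend removed, and KRT18 was 0.0044 with no scaling. The cause was not tested for any change given here. Over the other 140 genes selected, 2388 of 2478 comparisons with a setting kept direction and side of the threshold, 69 lost the call, 14 gained it and 7 changed direction. Over the 35 lists, 512 of 559 did so, 17 lost the call, 16 gained it and 14 changed direction; all 10 lists past camera were lost with an estimated correlation. Depth and the number of libraries limit small changes, which simulated counts recovered less often than large ones.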

Other observations

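Families of genes grouped by symbol stem were tested after the data were seen. Of 211 families with at least 8 members, 4 passed camera with the preset correlation. The protocadherin beta cluster, cell adhesion genes known from neurons, held 15 tested genes, of which 5 rose and 0 fell, with a median log2 fold change of 0.28 (camera adjusted p = 0.0234; adjusted p = 0.984 with an estimated correlation). Keratin genes had 5 lower and 0 higher of 13, with a median of −0.30 (camera adjusted p = 0.00236; adjusted p = 0.877 with an estimated correlation). The other two families were the ribosomal protein stems RPL and RPS, with 17 and 10 genes lower and medians of −0.13 and −0.13 (camera adjusted p = 0.00148 and 0.00586; adjusted p = 0.984 for each with an estimated correlation). Members of these families are similar in sequence, and reads can be shared between them.

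Of the tests on chromosomal blocks and on 3′ UTR sequence, those on the order of genes, on the GC trend, on SMURF1 against its block and on 3′ UTR length and GC content were chosen only after the results were seen; the others had their bounds set before the result. A difference in copy number between the control and the SMURF1 hairpin lines may be a source of the blocks: in 7 of 7 blocks, the genes not used to find them, non-coding or with low expression, had a median with the sign of their block, as it predicts. A regional change in transcription predicts the same signs, so this test cannot favour either. The sizes were unequal, −0.03 against a block median of −0.16 on chromosome 3 and 0.53 against 0.33 on chromosome 17. Without strand, non-coding genes can also share reads with coding genes on the opposite strand. Chance order of genes is argued against for the largest window, since 0 of 1000 shuffles over positions gave a window median as large as the observed 0.451 (highest 0.270). That value does not cover the blocks with smaller medians. For those, segmenting 20 shuffles with the same limit on the median found 0 blocks on average. The GC trend of the libraries is argued against as the whole source, since the chromosome 7 block from 72.9 Mb kept a median of −0.27 with the trend removed, against −0.28 before, but other blocks shrank: chromosome 3 from −0.16 to −0.11, under the limit of 0.12 for a block, chromosome 14 from −0.17 to −0.12 and chromosome 1 from 58.7 Mb from −0.27 to −0.21. SMURF1, inside the chromosome 7 block from 72.9 Mb, lay at −0.52 relative to the other block genes, more than 2 of its standard errors below them. That is 69.7% of control once the block median was taken off. This bound leaves out the spread between genes of the block (scaled median absolute deviation 0.15). Of 285 other genes, 8 (2.81%) were as low, so copy number of the block alone is argued against as the whole of its fall, but not excluded. DNA was not analysed here, and a regional change in transcription after the fall of SMURF1 stays open as the biological explanation, since hairpin and line were not separated by this design.

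Genes with the sequence AGCTTCA in their 3′ UTR were slightly higher in shSMURF1, by 0.05 on the log2 scale over 1565 of 9976 genes, an effect 6.78 standard errors from 0 with 3′ UTR length and GC content in the regression, and 0 of 100 permutations of the values over genes reached it (highest 5.24), which argues against chance among the 7-base sequences. Without length and GC content in the regression it lay only 2.71 standard errors from 0, and the sequence was picked with them in it, so a part of length and GC content in the effect cannot be told apart. A control hairpin whose seed pairs with this sequence could lower such genes in shControl cells. The effect in 3′ UTRs exceeded that in coding sequence by 3.71 standard errors, while the reverse complement TGAAGCT had 0.35. The sequence was picked for its effect in these 3′ UTRs, which favours both gaps, so neither decides on this hypothesis of seed pairing. Genes with at least 2 sites exceeded genes with 1 site by 0.02 (0.0195) on the log2 scale, only 1.11 standard errors, so this hypothesis and its absence cannot be told apart; the hairpin sequences are not given in the sources used here. No 7-base sequence marked genes lower in shSMURF1 beyond chance, since the lowest, at −4.09 standard errors, was matched in 35 of 100 permutations.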
